A study of Caenorhabditis elegans with 2 samples.

How the data were processed

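Chromatin immunoprecipitation with sequencing (ChIP-seq) was carried out on whole Caenorhabditis elegans young adults of mixed sex, 63 hours after synchronization as starved L1 larvae, per the labels. The animals carried a transgene for CEBP-1 with a C-terminal GFP-FLAG tag, and the chromatin, sheared by sonication, was precipitated with an antibody against GFP. The series held 2 biological replicates of 1 group, numbered 3 and 7 in the labels. No test between groups was therefore possible, and peaks and genes within a list are not independent replicates.

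The authors deposited peak lists in the ce10 and ce11 builds of the genome. For each replicate, and for the pooled alignments of both, a list of 30000 peaks held peaks and background as input for the irreproducible discovery rate (IDR), a measure of how well replicates rank the same peaks. A further list held the optimal IDR-thresholded peaks, per the text files deposited with the lists. Per the same files, each list was derived from the alignments and 1 control file. Each peak carries a signal value, which the authors' peak caller computed relative to that control, and a −log10 q-value that is capped at 1 highest value per list, per the column order of the deposited narrowPeak format. The peak caller and the IDR threshold were not given in the sources used here. In both builds the optimal list equalled the pooled peaks of highest signal value, which was tested on the lists. The signal value is the authors' own and was used only to describe, rank or filter peaks within a list. The lists give no read counts, so the depth of each sample is unknown, and intervals on shares of peaks or genes (Wilson, 95%) cover counting error only.

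The ce11 lists were analysed with the WBcel235 assembly, which is the same sequence, and with Ensembl release 115 genes. The end of the last peak on each chromosome lay within the chromosome's length. The ce10 lists were compared only with each other. Coordinates are 1-based. For each optimal peak, the strongest summit within 100 bp in each replicate list gave that replicate's signal value. It was divided by the median over optimal peaks, 204 in replicate 3 and 112 in replicate 7, and is given as relative signal, mean ± SD over the 2 replicates. The median relative signal is thus 1 in each replicate by construction.

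Replicate agreement was the share of optimal peaks with a summit within 100 bp among the top N peaks of each replicate, N being the number of optimal peaks. A promoter ran from 1000 bp upstream to 200 bp downstream of the annotated 5′ end of a protein-coding gene. Each summit was assigned to the first class that applied among promoter, 5′ UTR, coding exon, 3′ UTR, intron, non-coding gene and intergenic. Shares were compared with 1000 circular shifts of all summits along each chromosome (two-sided permutation test). For 29 gene lists, members with and without a promoter summit were compared with all other protein-coding genes (two-sided Fisher's exact test, Benjamini-Hochberg adjustment over the lists). The lists covered the DLK-1 and KGB-1 cascades, the p38 PMK-1 pathway, immune effectors, bZIP factors, 3 detoxification families, chaperones, 2 ribosomal protein classes, oxidative phosphorylation, the proteasome, tRNA synthetases, collagens, histones, nuclear hormone receptors, homeobox factors, neuropeptides, 6 sets of tissue markers, autophagy, lipid metabolism, insulin and TOR signalling, oxidative stress and the cell cycle. For 9 fixed motifs and for all 8-mers found in at least 10 peaks, windows of 50 bp on each side of the summit were compared with windows of equal width 300 bp away (exact McNemar test, Benjamini-Hochberg adjustment within each family). The C/EBP core was also compared between the strongest 25% and the weakest 25% of peaks (two-sided test with 100000 permutations). Genes on the X chromosome were compared with autosomal genes by Fisher's exact test. Around cebp-1, the number and median signal of listed peaks in 40 kb were ranked among 10000 random windows.

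The genes named were those with a promoter summit among the 25 strongest peaks, up to 4 members of each list with the strongest promoter peak, and cebp-1, sek-1, pmk-1, nipi-3, dlk-1, pmk-3 and cebp-2. This rule, the lists, the motifs, the tests and the alternatives given next were fixed before the data were examined. The alternatives were the ce10 build, other summit distances, narrower and wider promoters, promoters of all genes, the 50% of peaks with the highest signal, each replicate's own top N peaks, the nearest gene only, random lists matched on upstream intergenic length, a 100 bp motif window, shuffled windows or promoters without a peak as background, the strongest and weakest 10% of peaks, a 20 kb window and the top 10000 peaks. All work on the sequences TTGCGAAA and AGACGCAG beyond the search over all 8-mers was chosen after that search was seen. So were 1 summit per interval, leaving out peaks near tRNA genes, and peaks found in both replicates.

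Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. The promoter, 8-mer, motif, gene list and motif-against-strength tests were tested on simulated data. Replicate agreement, the X comparison and the cebp-1 windows were not. With 5982 random summits, of which 10% were moved into promoters, the promoter test found 100 of 100 shifts and called 5 of 100 unchanged sets. The 8-mer search found 20 of 20 planted sequences and called 0 of 17059 unplanted ones. The motif test found 100 of 100 planted C/EBP cores and called 7 of 900 unplanted motifs in 5982 windows. In the 8-mer and motif simulations summits lay at random in the genome. False calls from a composition that differs between summits and flanks were therefore not covered. Over 19973 genes, the list test found 85 of 100 lists planted at an odds ratio of 4 and called 2 of 2900 unplanted lists. Simulated peaks were given to genes independently, unlike real peaks, which neighbouring genes can share. The test of motif against strength found 97 of 100 planted differences and called 4 of 100 absent ones in 2990 peaks. After the first runs the random streams of these simulations were separated and their number was raised, and the values given are from those final runs.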

Results

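The binding of CEBP-1, a bZIP transcription factor of the C/EBP family known for its part in axon regrowth and stress responses, was mapped by ChIP-seq in whole young adult C. elegans. The tagged protein was precipitated through GFP from 2 biological replicates, 3 and 7, which form 1 group. The depth of each sample is unknown because the lists give no counts. The comparisons that the design allows are between the replicates, between regions of the genome, between gene groups and between sequences at and beside the summits.

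The optimal set held 5982 peaks in 5654 intervals, of which 5383 had 1 summit and 271 had more. Median interval width was 430 bp. The authors' signal value, used here only to describe, rank or filter within a list, had a median of 299 and ran from 148 to 20103 (20103.4). Chromosome III carried the most peaks per megabase, 80.7, followed by I with 70.3. Chromosome V had the fewest, 46.5, and the X chromosome had 57.7. The separate optimal list on ce10 held 6131 peaks.

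Of the optimal peaks, 60.2% had a summit within 100 bp among the top 5982 peaks of both replicates. Replicate 3 held 85.3% and replicate 7 held 72.2%, while 163 peaks (2.72%) were in neither. Within this rank limit both replicates held 95.9% of the strongest 1495 and 11.0% of the weakest 1496, which lie at the limit itself. Among all 30000 listed peaks, with no such limit, replicate 3 held 92.8% of the weakest 25% of peaks on the autosomes and 95.3% on the X chromosome, and replicate 7 held 85.2% and 81.2%. Compared directly, 60.9% of the top peaks of replicate 3 had a top peak of replicate 7 within 100 bp, against a mean of 1.22% over 100 circular shifts. Across the 5251 peaks matched in both replicates, Spearman's rank correlation of the signal was 0.615. This correlation is across peaks, which are not independent replicates, and no p-value is given for it.

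**Figure D1:**
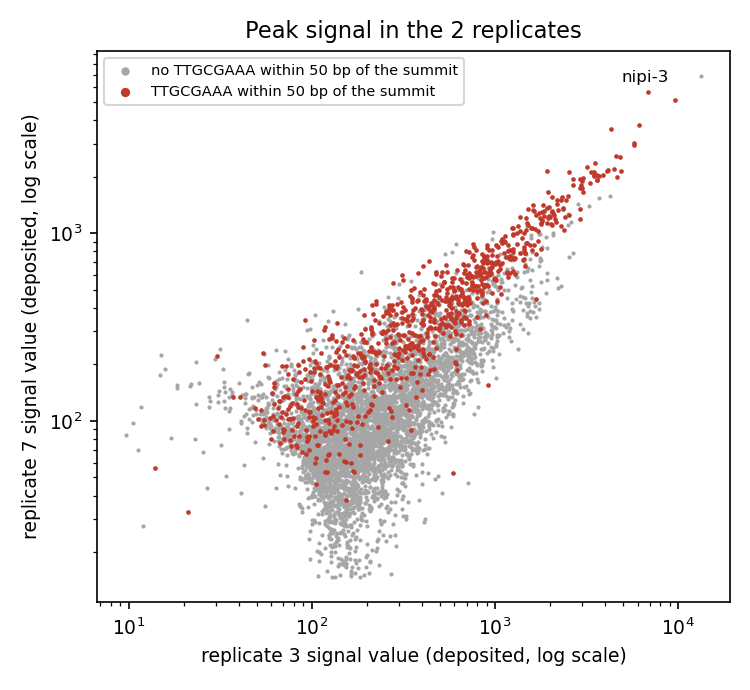
Deposited signal value of each matched optimal peak in replicate 3 (horizontal, log scale) and replicate 7 (vertical, log scale), with red points for peaks with TTGCGAAA within 50 bp of the summit and grey points for the rest. The peak upstream of nipi-3 has the highest value on both axes, and Spearman's rank correlation over the 5251 peaks is 0.615.

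The strongest peak of all lay upstream of nipi-3 (WBGene00010700), which encodes a Tribbles-family pseudokinase that acts in innate immunity. It covered X 15606780 to 15608212 in ce11, with its summit 267 bp upstream of the gene's 5′ end. Its relative signal was 63.6 ± 2.65 (mean ± SD, n = 2 replicates, as for all relative signals), and it ranked 1 in each replicate. Next among promoters came ftt-2, a 14-3-3 protein (42.2 ± 11.9), and tbb-2, a beta tubulin (32.0 ± 2.50). A single peak served icd-1, a subunit of the nascent polypeptide-associated complex, and vps-32.1, an ESCRT-III component (27.8 ± 0.782). The peak of Y37B11A.3 followed with 27.2 ± 1.11. Its summit lay inside another protein-coding gene, rev-3, and those of ftt-2 and tbb-2 lay inside the non-coding genes F52D10.7 and C36E8.10. Peaks were assigned by promoter position alone, and which gene a peak acts on was not tested.

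The peak of xbp-1, the transcription factor of the endoplasmic reticulum unfolded protein response, covered III 4193388 to 4194155 with its summit 30 bp upstream. It ranked 9 with a relative signal of 22.8 ± 0.571. Peaks of gei-4 (21.6 ± 3.47), hat-1, a histone acetyltransferase (20.4 ± 3.48), frm-10, a FERM domain protein (18.6 ± 0.510), and eef-1A.2, a translation elongation factor (17.5 ± 4.62), were also among the 25 strongest. So were those of cel-1, the mRNA capping enzyme, which shares its peak with the nucleoporin gene npp-14 (18.1 ± 0.137), abhd-5.2 (18.1 ± 0.396), unc-116, a kinesin heavy chain (17.5 ± 0.359), snb-1, synaptobrevin (17.5 ± 0.315), C05G5.2 (17.6 ± 0.867) and C01A2.4 (17.6 ± 1.72). The hat-1 summit also lay inside the protein-coding gene M03C11.3, and the gei-4 summit inside the lincRNA gene linc-90. In all, 16 of the 25 strongest peaks were in promoters, those of 18 genes.

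The other 9 lay elsewhere. The second-ranked peak, with a relative signal of 46.5 ± 0.976, was intergenic at V 14199813 to 14200558, and its nearest protein-coding 5′ end, that of T16A9.3, was 5277 bp away. An interval at X 16929262 to 16932094 held the summits ranked 7 and 8. The peak ranked 11 lay 1812 bp upstream of hsf-1, the heat shock transcription factor. Introns of dhc-4, unc-33, a collapsin response mediator homolog, and Y43F8B.2 held the peaks ranked 14, 16 and 20. Without replicate 3, 17 genes had a promoter summit among the 25 strongest peaks, 15 of them shared with the 18, and without replicate 7 there were 18, of which 17 were shared.

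**Figure D2:**
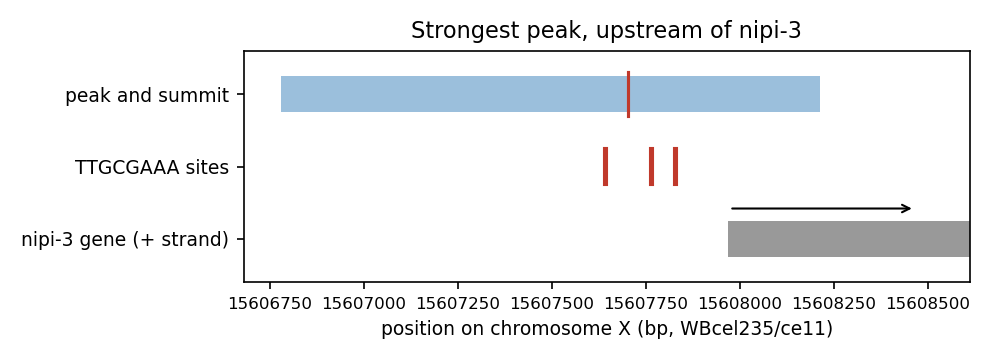
Map of the strongest peak on chromosome X (horizontal axis, position in bp, ce11), with the peak interval in blue, its summit and the TTGCGAAA sites in red, and the start of nipi-3 in grey with an arrow for its direction. The 3 sites lie on both sides of the summit inside the peak, the nearest 60 bp from it.

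Peaks were concentrated in promoters and depleted from coding sequence. Promoters of protein-coding genes held 2568 summits, 42.9% (95% interval 41.7 to 44.2), against 21.2% of shifted summits. Coding exons held 4.71% against 19.9%, and introns 24.4% against 31.1%. The 5′ UTR share was 1.22% against 0.816%, and the intergenic share of 21.2% did not differ from the shifted 21.3% (permutation p = 0.978). For promoters, coding exons and introns the two-sided permutation p was 0.001, the smallest they can give. Smaller differences were found for 3′ UTRs (2.84% against 2.395%, permutation p = 0.027, adjusted p = 0.0378) and non-coding genes (2.67% against 3.25%, permutation p = 0.034, adjusted p = 0.0397). Promoter peaks served 2980 of 19973 protein-coding genes (14.9%), and 655 peaks lay in the promoters of more than 1 gene, so genes are not independent of each other.

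**Figure D3:**
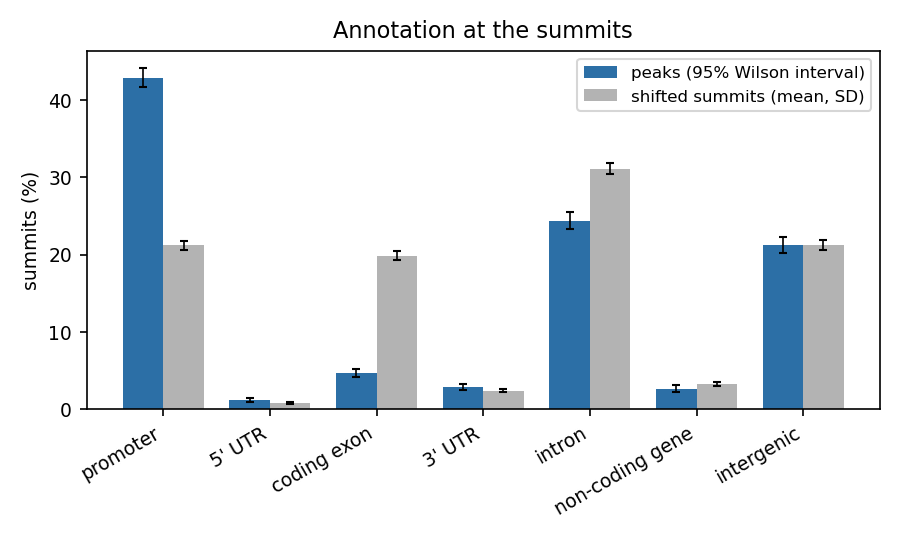
Share of summits (vertical axis, %) in each annotation class for the 5982 optimal peaks (blue, 95% Wilson interval) and for 1000 circular shifts (grey, mean with SD). Promoters hold 42.9% of summits against 21.2% after shifting, and coding exons 4.71% against 19.9%.

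Genes for small structural RNAs stood out among non-coding genes. Within 200 bp of tRNA genes there were 197 peaks, 12.04 times the shifted mean of 16.4. Near snoRNA genes, which guide RNA modification, there were 94 peaks (ratio 8.34), near snRNA genes of the spliceosome 28 (ratio 7.40) and near miRNA genes 19 (ratio 2.68). Genes of the ncRNA class had 714 peaks (ratio 3.48) and lincRNA genes 38 (ratio 1.99, permutation p = 0.003). The piRNA genes, with 46 peaks (ratio 0.263), and pseudogenes, with 52 (ratio 0.230), had fewer than shifted summits. For all of these except lincRNA the permutation p was 0.001, the smallest they can give. No peak was near an rRNA gene, against a shifted mean of 0.984 (permutation p = 0.741).

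Of the 29 gene lists, 10 had promoter peaks more often than other genes and 3 less often (Fisher's exact test with Benjamini-Hochberg adjustment). No untagged strain was analysed here, so peaks in the enriched lists cannot be told apart from immunoprecipitation signal that does not need the tagged protein. Cytosolic ribosomal proteins led, with a peak at 68 of 83 genes (odds ratio 26.4, 95% interval 14.9 to 49.8, adjusted exact p = 1.16e-40), among them rpl-3 (16.04 ± 3.08), rpl-35 (12.5 ± 2.61), rpl-15 (10.03 ± 4.25) and rpl-20 (9.56 ± 4.09). The proteasome, which degrades ubiquitinated proteins, had peaks at 22 of 33 genes (odds ratio 11.5, adjusted exact p = 3.26e-10), such as pas-3 (2.50 ± 0.454) and rpn-11 (2.14 ± 0.909). Oxidative phosphorylation had peaks at 28 of 52 genes (odds ratio 6.71, adjusted exact p = 6.76e-10), including ucr-2.1 (6.47 ± 0.588) and cox-5B (6.34 ± 1.75). Mitochondrial ribosomal proteins had peaks at 26 of 67 (odds ratio 3.64, adjusted exact p = 6.31e-06), the strongest at mrps-7 (5.51 ± 1.13).

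The tRNA synthetases, which charge tRNAs with amino acids, had peaks at 15 of 32 genes (odds ratio 5.05, adjusted exact p = 5.10e-05), with mars-1 (4.70 ± 0.812), ears-2 (3.25 ± 0.442) and hars-1 (2.64 ± 0.0522) among the strongest. Chaperones had peaks at 25 of 63 (odds ratio 3.77, adjusted exact p = 6.31e-06), such as unc-23 (7.22 ± 0.266), the Hsp70 gene hsp-1 (6.64 ± 0.710), dnj-13 (6.35 ± 1.08) and cct-8 (5.64 ± 3.18). Genes of autophagy and the lysosome gave the same count, 25 of 63, with vha-17, a proton pump subunit (8.26 ± 1.43), sqst-1, the p62 cargo receptor (8.17 ± 2.33), and the Atg8 homolog lgg-1 (6.36 ± 1.85). Cell cycle and replication genes had peaks at 26 of 72 (odds ratio 3.24, adjusted exact p = 2.34e-05), such as knl-2 (8.64 ± 1.73), rfc-4 (4.79 ± 1.78) and cdc-42 (4.48 ± 0.464). Among bZIP transcription factors, 10 of 30 had a peak (odds ratio 2.86, adjusted exact p = 0.0224), and besides xbp-1 these included atf-4 (2.48 ± 0.988), the mitochondrial stress factor atfs-1 (1.80 ± 0.838) and jun-1 (1.82 ± 0.535). Insulin and TOR signalling had peaks at 8 of 24 (odds ratio 2.86, adjusted exact p = 0.0429), led by the S6 kinase gene rsks-1 (5.71 ± 0.333).

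Collagens, neuropeptides and sperm proteins had few promoter peaks. Only col-38 (1.46 ± 0.540) and col-71 (0.945 ± 0.329) of 180 collagen genes had one (odds ratio 0.0634, adjusted exact p = 1.88e-09). The col-38 peak is also that of rpl-5, a cytosolic ribosomal protein gene. Neuropeptides and insulins had 4 of 144 (odds ratio 0.162, adjusted exact p = 1.02e-05), with ins-39 (4.35 ± 3.11), nlp-76, nlp-40 and nlp-4, and sperm proteins had 3 of 89 (odds ratio 0.198, adjusted exact p = 0.00219), with spe-48 (8.77 ± 0.178), spe-46 and spe-39. Without replicate 3 odds ratios lay nearer to 1 for cytosolic ribosomal proteins (17.1), the proteasome (4.20), mitochondrial ribosomal proteins (2.37), collagens (0.220, against 0.121 without replicate 7) and sperm proteins (0.382). With the 2991 strongest peaks the proteasome gave 3.73, mitochondrial ribosomal proteins 2.17, collagens 0.110 and sperm proteins 0.345, and with peaks found in both replicates cytosolic ribosomal proteins gave 15.6, the proteasome 3.42, mitochondrial ribosomal proteins 2.41 and collagens 0.101. When a peak counted for the nearest gene only, cytosolic ribosomal proteins gave 7.56, chaperones 1.99 and collagens 0. The wide promoter gave 0.119 for collagens, 0.246 for neuropeptides and 0.358 for sperm proteins, and the narrow one 0.108 for neuropeptides. The call for chaperones was lost when a peak counted for the nearest gene only (adjusted exact p = 0.100), that for bZIP factors with peaks found in both replicates (odds ratio 2.77, adjusted exact p = 0.0596), that for sperm proteins without replicate 3 (adjusted exact p = 0.0629) and with the 2991 strongest peaks (adjusted exact p = 0.118), and that for insulin and TOR signalling under 4 alternatives that take other promoters or peaks by strength or replicate (odds ratios from 2.15 to 2.61, adjusted exact p from 0.103 to 0.210). Restricted after the data were seen to peaks with TTGCGAAA, described with the sequences, the comparison called 1 list; with the remaining peaks it called 11, without bZIP factors (odds ratio 2.45, adjusted exact p = 0.109) and insulin and TOR signalling (odds ratio 2.77, adjusted exact p = 0.0688), and the odds ratio of tRNA synthetases was 3.06.

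**Figure D4:**
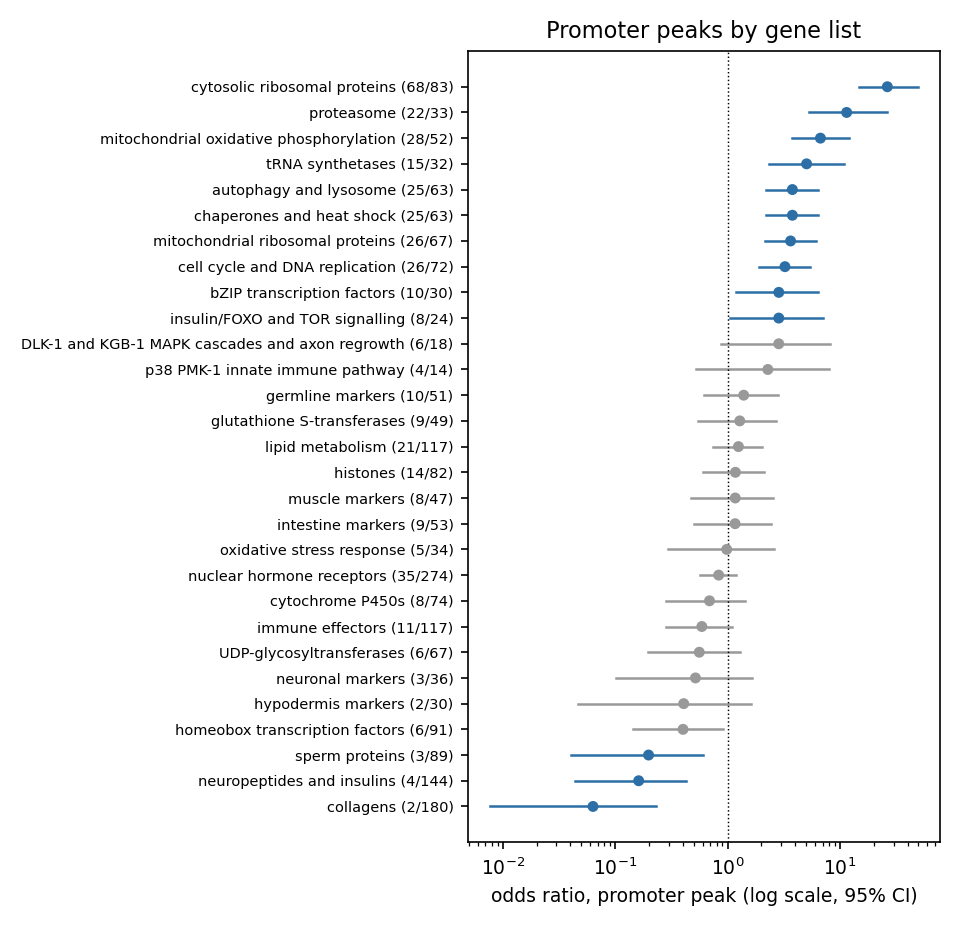
Odds ratio of each gene list for a promoter peak (horizontal axis, log scale, points with 95% intervals), with the number of members with a peak over all members beside each name. Blue lists passed the adjusted threshold of 0.05, from cytosolic ribosomal proteins at 26.4 to collagens at 0.0634, and grey lists did not.

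The pathways through which CEBP-1 is best known had peaks at part of their members. In the DLK-1 and KGB-1 cascades, which act in axon regrowth, 6 of 18 genes had a promoter peak (odds ratio 2.85, adjusted exact p = 0.0790). They included svh-2, a receptor tyrosine kinase (3.23 ± 0.658), the kinase genes mak-2 (1.81 ± 0.480) and kgb-1 (1.27 ± 0.563), and mlk-1, whose peak ranked 2108. In the p38 PMK-1 pathway, 4 of 14 had one (odds ratio 2.28, adjusted exact p = 0.246), namely nipi-3, rab-1 (2.34 ± 1.15), wts-1 and skn-1 (0.525 ± 0.103). No promoter peak was found for cebp-1 itself, its relative cebp-2, or the kinase genes dlk-1, pmk-3, pmk-1 and sek-1. The first list passed the threshold against random lists matched on upstream length (adjusted permutation p = 0.0365), with the wide promoter (adjusted exact p = 0.00615), with the strongest peaks (adjusted exact p = 0.0445) and without replicate 7 (adjusted exact p = 0.0309). The second passed with the wide promoter (odds ratio 4.21, adjusted exact p = 0.0158), and with peaks found in both replicates its odds ratio was 1.515 (adjusted exact p = 0.888).

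Immune effectors had peaks at 11 of 117 genes (adjusted exact p = 0.212), 1 of which, irg-2, an infection response gene, was strong (16.2 ± 1.86, rank 29). With the 2991 strongest peaks this list passed as depleted (odds ratio 0.172, adjusted exact p = 0.00619), as it did with the wide promoter (odds ratio 0.524, adjusted exact p = 0.0401). Homeobox factors had 6 of 91 (odds ratio 0.401, adjusted exact p = 0.0531; with the wide promoter 0.349, adjusted exact p = 0.00615, and without replicate 3 0.619, adjusted exact p = 0.319), and nuclear hormone receptors 35 of 274 (adjusted exact p = 0.456), the strongest at nhr-56 (7.56 ± 0.465). The homeobox count includes unc-37, a corepressor gene whose product has no homeodomain, and the comparison was not repeated without it. Of the detoxification families, cytochrome P450s had 8 of 74 (adjusted exact p = 0.499), with cyp-33C8 at 6.74 ± 0.378, glutathione S-transferases 9 of 49 (adjusted exact p = 0.608), with gst-38 at 4.23 ± 0.735, and UDP-glycosyltransferases 6 of 67 (odds ratio 0.560, adjusted exact p = 0.366), which became 0.413 with the wide promoter (adjusted exact p = 0.0452) and 0.872 without replicate 3 (adjusted exact p = 0.922). Lipid metabolism had 21 of 117 (adjusted exact p = 0.456), including dgat-2 (6.80 ± 0.358) and the perilipin gene plin-1 (5.04 ± 0.161). It passed as enriched without replicate 7 (odds ratio 1.699, adjusted exact p = 0.0401) and with the wide promoter (odds ratio 1.95, adjusted exact p = 0.00296), while the strongest peaks gave 0.825 and replicate 7 alone 0.946. Histones had 14 of 82 (adjusted exact p = 0.608) and oxidative stress genes 5 of 34 (adjusted exact p = 1). Markers of the germline (10 of 51), intestine (9 of 53), muscle (8 of 47), neurons (3 of 36) and hypodermis (2 of 30) had adjusted exact p from 0.456 to 0.723. A p that misses the threshold does not show that these lists match other genes.

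The C/EBP core, TTRCGYAA, was found within 50 bp of 76 summits, 1.27% (95% interval 1.02 to 1.59), against 0.435% of flanks (McNemar test, adjusted exact p = 1.67e-06). Its palindromic form TTGCGCAA was found at 0.669% against 0.100% (adjusted exact p = 9.31e-07). The C/EBP-ATF composite TGATGCAA (0.819% against 0.351%, adjusted exact p = 0.00164) and the AP-1 site (1.81% against 1.12%, adjusted exact p = 0.00274) were also more frequent at summits. GAGA repeats were found at 4.88% against 1.42% (adjusted exact p = 2.28e-27) and the E-box CACGTG at 5.52% against 2.01% (adjusted exact p = 2.56e-24). The PAR bZIP site was less frequent (0.368% against 0.853%, adjusted exact p = 0.00164), and the CRE (adjusted exact p = 0.0819) and GATA sites (adjusted exact p = 0.124) did not pass. With shuffled windows as background the C/EBP core was enriched 1.52 times rather than 2.92 times (adjusted exact p = 0.0418), the palindrome 1.74 times rather than 6.67 times (adjusted exact p = 0.0467), the composite (1.44 times, adjusted exact p = 0.139) and AP-1 (1.24 times, adjusted exact p = 0.148) lost their calls, and CRE (adjusted exact p = 5.05e-10) and GATA (adjusted exact p = 1.34e-12) gained them. CRE also passed with the 100 bp window (adjusted exact p = 0.0465) and without replicate 7 (adjusted exact p = 0.00853), as did GATA (adjusted exact p = 0.00458 and 0.00959), whose difference was negative without replicate 3 (-1.06 percentage points, adjusted exact p = 0.165). Without replicate 3 the PAR bZIP call was lost (0.570% against 0.888%, adjusted exact p = 0.0681), and the E-box was found at 3.99% against 1.68% and the palindrome at 0.637% against 0.184%. AP-1 was found at 2.34% against 0.936% in the strongest peaks, and with the 100 bp window AP-1 stood at 3.61% against 2.34% and GAGA repeats at 8.88% against 2.57%.

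The search over all 8-mers was led by TTGCGAAA. It is not among the forms of the C/EBP core, but it matches the palindrome TTGCGCAA except for A in place of the last C. It was found within 50 bp of 889 summits (14.9%) and in 63 flanks (1.05%; adjusted exact p = 3.38e-201). The next sequences, ATTTCGCA at 705 summits and ATTGCGAA at 595, overlap it. AGACGCAG followed with 400 summits against 52 flanks (adjusted exact p = 1.24e-67), and GAGACGCA, which overlaps AGACGCAG, with 379 against 50. Runs of A and T were depleted, such as AAAAAATT at 250 summits against 654 flanks. Of 19675 8-mers tested, 2013 were more frequent at summits and 1144 less frequent. How many of these calls follow from base composition that differs between summits and flanks was not tested. Without replicate 3, 1053 were more frequent, 818 of them among the 2013. TTGCGAAA led the search with a 100 bp window, in the 2991 strongest peaks and in the top peaks of each replicate.

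Stronger peaks held TTGCGAAA far more often. It was found in 35.1% of the strongest 1495 peaks (95% interval 32.7 to 37.5) and in 5.55% of the weakest 1495, with a permutation p of 1e-05, the smallest they can give. In the pooled list the share was 64.4% at ranks 1 to 250 and 29.4% at ranks 501 to 1000. At ranks 1 to 250 it was 57.2% in replicate 3 and 79.7% in replicate 7. Of the 25 strongest peaks, 23 had the sequence within 50 bp of the summit, and those of nipi-3 and eef-1A.2 did not. The nipi-3 peak held 3 copies farther out, starting at X 15607638, 15607761 and 15607824. In the xbp-1 peak a copy starting at III 4193757 was centred 18 bp from the summit. The C/EBP core was found in 2.07% of the strongest and 1.14% of the weakest 1495 peaks (permutation p = 0.057). Without replicate 7 this difference passed the threshold (permutation p = 0.0088). The tests of TTGCGAAA against strength were chosen after it had led the 8-mer search.

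**Figure D5:**
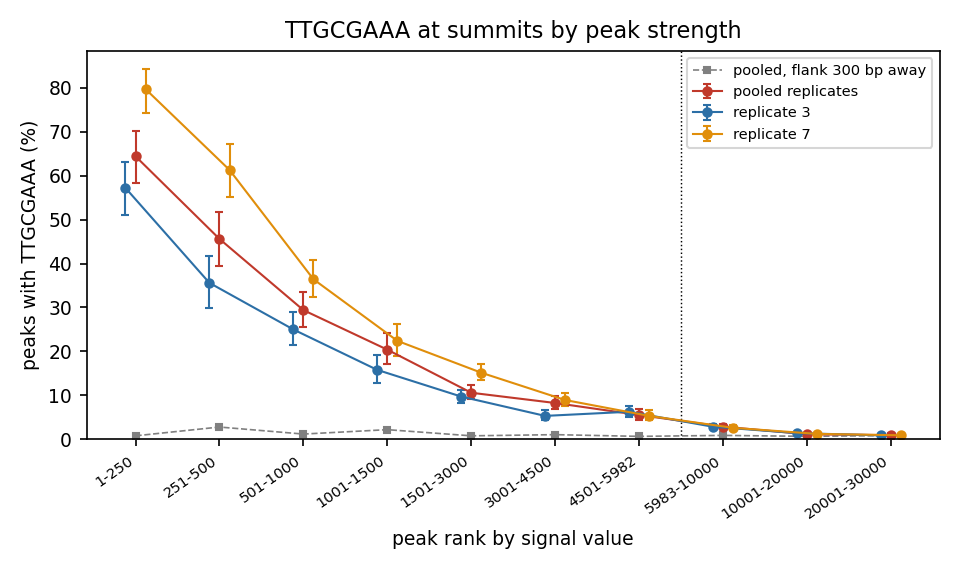
Share of peaks with TTGCGAAA within 50 bp of the summit (vertical axis, %, 95% Wilson intervals) against peak rank by signal value (horizontal axis) in the pooled list (red), replicate 3 (blue) and replicate 7 (orange), with flanks 300 bp away in the pooled list (grey squares). The dotted line marks the end of the optimal set, and the pooled share is 64.4% at ranks 1 to 250 and 0.95% at ranks 20001 to 30000.

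Genes on the X chromosome had promoter peaks less often than autosomal genes. A peak was found at 326 of 2731 X genes (11.9%) and at 2654 of 17242 autosomal genes (15.4%; odds ratio 0.745, 95% interval 0.657 to 0.843, Fisher's exact p = 1.56e-06). Autosomes differed among themselves, from 10.5% of genes on V to 23.03% on III. Without replicate 7 the call was lost (odds ratio 0.924, Fisher's exact p = 0.174), and without replicate 3 the odds ratio was 0.664 (Fisher's exact p = 3.86e-10). The call was kept with the 2991 strongest peaks (odds ratio 0.822, Fisher's exact p = 0.00915). It was also kept with peaks found in both replicates (odds ratio 0.775, Fisher's exact p = 4.97e-04).

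Peaks around cebp-1, the gene carried by the transgene, were examined because its locus can be present in extra copies. The 40 kb around the gene on X held 15 listed peaks in replicate 3 and 11 in replicate 7, counts that 67.6% and 53.6% of random windows did not exceed. Their median signal stood at percentile 87.3 in replicate 3 and 83.0 in replicate 7 among random windows with a peak, but at 44.8 and 46.9 with the top 10000 peaks only. The 20 kb around cebp-1 held 0 listed peaks in either replicate. In the pooled list the gap over the gene ran from X 1440565 to 1469439, and 898 of 21505 gaps were at least as long, which together covered 52.2% of the genome. This is 1 locus, so no test was made.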

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

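The tests of TTGCGAAA in this part were chosen after it had led the search over 8-mers, although the bound for shuffled windows was written before those windows were counted. The list of replicate 7 held 13 peaks on the mitochondrial genome and those of replicate 3, the pooled alignments and the optimal set held none. The strongest of the mitochondrial peaks ranked 6 in the list of replicate 7, with a signal value of 3449.4 at M 4362 to 4959. They count in the ranks of replicate 7 and among its top peaks in the measures of replicate agreement. Where its top peaks replaced the optimal set, they were left out.

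Below the IDR threshold, peaks that enter no comparison of the optimal set still held TTGCGAAA at their summits more often than beside them. Of 24018 such peaks in the pooled list, 327 had it within 50 bp of the summit, 1.36% (95% interval 1.22 to 1.52), against 0.791% of flanks (ratio 1.72, exact McNemar p = 8.33e-10). At ranks 5983 to 10000 the share was 2.89% against 0.896% of flanks, and at ranks 20001 to 30000 it was 0.95% against 0.860%.

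Among the strongest 1000 peaks, 42.2% held TTGCGAAA, and 81.1% of the 562 sites within 300 bp of their summits lay within 50 bp, at a median distance of 18 bp. The base and dinucleotide composition of the summit sequences was weighed as a technical explanation. Shuffled windows that keep both held the sequence in 0.7% (95% interval 0.339 to 1.44), which argues against composition as the source. No biological explanation was tested, since the design has 1 group. Whether another protein at these sites could carry the signal stays open, as no other factor or untagged strain was analysed here.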

How the results depend on the processing

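Of the alternatives, those that restrict peaks by TTGCGAAA or AGACGCAG, take 1 summit per interval, leave out peaks near tRNA genes or keep peaks found in both replicates were chosen after seeing the data. The promoter share kept its direction and call under each alternative (40.3% and 44.3% without 1 replicate), as did the C/EBP core and TTGCGAAA. Replicate agreement was 51.7% within 50 bp, 67.5% for any overlap and, under the same rank limit, 89.9% for the 2991 strongest peaks, and Spearman's correlation was 0.668 within 50 bp and 0.596 for the strongest; the cause was not tested. Lists past the threshold numbered 13, between 11 and 19 under the other alternatives, but 1 with TTGCGAAA peaks only and 0 with AGACGCAG peaks only, where 457 and 233 genes had a peak. The wide promoter brought immune effectors, UDP-glycosyltransferases, homeobox factors and lipid metabolism past the threshold, with adjusted exact p from 0.00296 to 0.0452, at odds ratios of 0.524, 0.413, 0.349 and 1.95. Without replicate 3 UDP-glycosyltransferases gave 0.872 and homeobox factors 0.619, neither past the threshold. Immune effectors also passed with the strongest peaks (0.172, adjusted exact p = 0.00619) and lipid metabolism without replicate 7 (1.699, adjusted exact p = 0.0401). More frequent 8-mers numbered 1298 in the strongest peaks, where 8723 were tested, and 1053 to 2428 without 1 replicate. The difference in the C/EBP core between strong and weak peaks was 0.804 to 1.27 percentage points without 1 replicate, and the X odds ratio 0.664 to 0.924. At cebp-1 the count percentile was 36.1 (replicate 3) and 27.2 (replicate 7) in 20 kb, and 91.8 and 83.3 for the top 10000 peaks, where the median signal stood at 44.8 and 46.9; 20 kb held no peak to rank by signal. The following reversals were all of values that had not passed the threshold, except mitochondrial ribosomal proteins and insulin and TOR signalling, and none passed it after reversing. With TTGCGAAA peaks only, odds ratios were 1.19 for P450s, 0.889 for glutathione S-transferases, 0.646 for mitochondrial ribosomal proteins, 0 for histones and intestine markers, 2.52 for neuronal, 0.854 for germline and 0.928 for muscle markers. With AGACGCAG peaks only they were 0 for the p38 pathway, intestine markers and insulin and TOR signalling, 1.16 for P450s, 1.28 for UDP-glycosyltransferases, 2.26 for nuclear hormone receptors, 2.43 for neuronal markers and 0.729 for lipid metabolism. Without TTGCGAAA peaks oxidative stress gave 1.16. With the strongest peaks they were 1.04 for P450s, 0.881 for glutathione S-transferases, 0.643 for histones, 0.809 for intestine markers and 0.825 for lipid metabolism. Leaving out 1 replicate gave 0.731 to 1.21 for glutathione S-transferases, 0.746 to 1.81 for histones, 0.670 to 1.94 for intestine markers, 0.946 to 1.699 for lipid metabolism and 0.858 to 1.15 for oxidative stress. Peaks found in both replicates gave 0.807 for glutathione S-transferases, 0.465 for histones, 0.356 for intestine markers and 0.666 for lipid metabolism. The narrow promoter gave 0.607 for histones and 1.33 for oxidative stress, and the wide one 0.941 for histones and 1.202 for neuronal markers. The nearest gene gave 0.494 for histones, 1.05 for nuclear hormone receptors and 0.829 for germline markers. Against matched random lists the ratio was 0.761 for histones and 1.01 for oxidative stress. The GATA difference was -0.819 percentage points against promoters without a peak, -1.81 in the strongest peaks and -1.06 to 1.99 without 1 replicate. The cause of these changes was not tested. Of 125 named genes, 10 lacked a promoter peak without replicate 3 and 3 without replicate 7. No paired analysis was possible because there is 1 group. Depth is unknown, so its effect was not tested.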

Other observations

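Except for the bounds written beforehand for unmatched promoter peaks and tRNA copies, the tests in this part were chosen after the patterns had been seen. AGACGCAG, the leading 8-mer that does not overlap TTGCGAAA, marked a largely separate set of peaks. It was found at 2.92% of the 889 summits with TTGCGAAA and at 7.34% of the 5093 without it. Its share was 9.57% in the strongest 1495 peaks and 4.88% in the weakest 1496. Promoters (7.36%), introns (6.10%) and intergenic summits (8.11%) held it at shares above the 0.709% of coding exons, and 0 of 197 peaks near tRNA genes had it, which allows a share of up to 1.91%. None of the 29 gene lists passed the adjusted threshold among the 233 genes with such a promoter peak.

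The bases beside TTGCGAAA were uneven. Over 451 sites in the strongest 1000 peaks, the base before it was A at 69.0% and G at 24.6%, and the base after it was T at 79.2%. The 9-mer TTGCGAAAT alone was found at 33.8% of these summits against 0.6% of flanks. Matched peaks with TTGCGAAA had a median rank of 1351 in replicate 3 and 720 in replicate 7, and those without it 3123 and 3690.

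Peaks at tRNA genes and at cytosolic ribosomal protein genes rarely held TTGCGAAA. It was found at 0 of 197 peaks near tRNA genes and at 2 of 65 ribosomal protein peaks, while peaks drawn elsewhere at the same strength held it at 13.3% and 21.7%. Lower strength is argued against, since 1e-04, the smallest permutation p they can give, was reached in both cases. Counted per gene, 2 of 83 cytosolic ribosomal protein genes (2.41%) had a promoter peak with TTGCGAAA, against 2.29% of other genes (odds ratio 1.05). The low share among their peaks thus goes with many peaks that lack the sequence. Reads shared between identical tRNA copies cannot be told apart from other sources: 20.3% of 143 single-copy tRNA genes and 39.7% of 469 with identical copies had a peak, a ratio of 0.511 (95% bootstrap interval 0.351 to 0.691) that spans the bound. Immunoprecipitation signal at highly transcribed genes may also contribute, with an odds ratio of 26.7 for ribosomal protein genes among peaks without TTGCGAAA, and it stays open because no untagged strain was analysed here; no biological explanation was tested.

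The X chromosome held 16.2% of the listed peaks of replicate 3 and 9.91% of those of replicate 7, and 17.8% and 6.98% of those with no partner in the other replicate. Replicate 7's own peaks leaned more towards promoters, 22.9% against 20.1%, a difference of 2.82 percentage points (95% interval 1.958 to 3.69) that was below the bound of 5 written beforehand; it is argued against as the whole source, since with the promoter share of replicate 3, the X share of replicate 7's own peaks was 7.04%, a difference of -10.8 percentage points (95% interval -11.5 to -10.1). A lower X copy number in the animals of replicate 7, which were of mixed sex, cannot be told apart from other sources: among peaks matched in both replicates, X peaks shifted in rank by 0.348 percentile points against autosomal ones among the strongest 25% of peaks (95% bootstrap interval -1.74 to 2.402), by 5.43 (-6.81 to 14.8) in the next 25%, but by -12.8 (-25.8 to -5.83) and -18.9 (-27.99 to -5.38) in the weaker 25% groups, of ranks beyond 2991. Peaks missing from either list are left out of these shifts, and from the strongest to the weakest 25% replicate 7 listed 94.6%, 90.0%, 79.2% and 81.2% of X peaks against 98.8%, 96.8%, 91.5% and 85.2% of autosomal ones, while replicate 3 listed from 95.3% to 99.3% of X peaks and from 92.8% to 97.7% of autosomal ones. No biological explanation was tested.

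With only peaks that hold TTGCGAAA, 457 genes had a promoter peak and tRNA synthetases were the 1 list past the threshold. Of 32 members, 6 had such a peak (odds ratio 9.97, 95% interval 3.34 to 24.9, adjusted exact p = 0.00220), at mars-1, ears-2, pars-1, iars-1, aars-2 and rars-1. That such peaks may favour tRNA synthetase genes is a hypothesis drawn from this value, which is therefore no test of it, and no independent data were analysed here. Of the 6 genes, pars-1 had a peak with no summit within 100 bp in the list of replicate 3. With only peaks that lack TTGCGAAA, 11 lists passed, and cytosolic ribosomal proteins again had the highest odds ratio. The proteasome (20 of 33 genes, odds ratio 10.4), oxidative phosphorylation (27 of 52, 7.32) and mitochondrial ribosomal proteins (25 of 67, 4.03) were among them. Of their genes, 2, 2 and 1 had a promoter peak with the sequence. Signal that does not need the tagged protein therefore stays open for these lists too.

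A second hypothesis was that strong peaks in introns may hold TTGCGAAA more often than strong peaks in promoters. Among the strongest 1000 peaks, 51.3% of 191 intronic and 39.4% of 559 promoter summits had it (Fisher's exact p = 0.00506). The comparison was picked among the classes because these shares differed, so the p is no test of the hypothesis, which stays open.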
